A study of Caenorhabditis elegans with 8 samples.

How the data were processed

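Small RNA reads of 8 samples were used, in 7 groups: wild-type adults, wild-type adults after beta elimination (2 samples), embryo input, ERGO-1 IP from embryos, and ergo-1, rrf-1 and rrf-3 adults. The values are expected counts: per the file headers and the labels, the authors matched small RNA sequences to the genome and divided the reads of each sequence over its genomic places. The tools, their versions and the genome build used for that are not given in the sources used here. The files of both beta-elimination samples were identical byte for byte, so they were used as 1 library, and no group had a second library to give a spread.

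Everything below was computed from these values with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9, with seed 1. Genes came from the Ensembl release 115 annotation. Positions in the files differed from that annotation: in 403 windows of 250000 bp with at least 200 sequences, the shift that fitted best was -10 to 120 bp in 391 and 4600 bp in 5 windows at the end of chromosome V. In 7 other windows it was -20 to 6000 bp; with each 1000 bp and strand counted as at most 20 sequences, 4 of them came inside the tolerance and 3 did not. Genes in those 3 were kept, and of the genes named in the text only T05E12.8 lies there (chromosome V, 17000001 to 17250000). Positions were therefore not converted. A read was given to a gene only where the gene was the same at every difference from -10 to 130 bp, and no gene was named on chromosome V beyond file position 19500000. This left a named stretch for 21843 of 22295 genes. Where several genes carried 1 name, another name was used (2359 genes). Coordinates in the text are file positions.

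Sequences of the reads and a genome sequence were not used here, so the initial nucleotide of a read was not known. The classes planned as 26G-RNA, 22G-RNA and 21U-RNA were therefore defined by length and place alone, which departs from the plan: 26 nt antisense to a named gene, 21 to 23 nt antisense to a named gene, and 21 nt in those 60 stretches of 100000 bp on chromosome IV that hold 14345 of 15363 annotated 21U-RNA genes. The first of these can hold antisense RNAs of other kinds. The last was counted on either strand and took precedence over the second. In those 60 stretches the second class therefore held reads of 22 and 23 nt only, and the last can hold 21-nt RNAs of other kinds. Reads with a genomic span above 35 nt were left out. Structural RNA made up 0.670% of wild-type reads, 0.728% after beta elimination, 2.49% of input, 4.71% of the IP, 28.4% of ergo-1, 19.8% of rrf-1 and 24.5% of rrf-3, and was taken out of the denominator of every share.

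Ratios of shares were given with exact conditional binomial (Clopper-Pearson) 95% intervals. With 1 library per group no test across libraries was made. Genes were called by a fixed rule of size. For 26-nt reads it asked for at least 10 reads in both libraries together and an interval wholly above 2 or below 0.5; for 22-nt reads it asked for at least 50 reads, scaled to all 22-nt reads. Members of gene lists were called by the same interval from 10 reads on. IP target genes are those with an IP/input interval wholly above 2 for 26-nt reads. A count of 0 gave a fold against a floor of 3 reads. Genes were named by rule: the 10 largest in each direction by the end of the interval nearest 1, the 10 IP target genes with most reads, and the 4 members of each list with most reads. Other genes are said to have been chosen after their values were seen.

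Gene lists were the literature list of ERGO-1 targets (33 of 35 members matched), spermatogenesis genes (84 of 84), oogenic germline and maternal genes (69 of 69), somatic genes (60 of 60), small-RNA pathway genes (54 of 57), and annotated pseudogenes (2128). For members with at least 10 reads of 22 nt, the median log2 ratio was set beside 10000 random lists of the same size drawn from genes of like level in 20 bins; no percentile was given for fewer than 5 members. The percentile is the percent of random lists with a lower median. The groups, comparisons, lists, rules of size and most alternatives were fixed before the data were examined.

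The part of the IP library that resembled adults was estimated by fitting its 22-nt reads per gene as a sum of other libraries with coefficients of at least 0, with weights taken from fitted values and refitted 50 times. An earlier form of this fit, with weights from observed counts, gave coefficients too low on simulated data and was replaced for that reason. On simulated data the form used gave 0.393 and 0.0997 for true values of 0.4 and 0.1, and 0 for the ergo-1 library where none had been put in.

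The rules of size were tested on simulated data at the depth of these libraries. For 22-nt reads, 90% (ergo-1/rrf-1), 90% (rrf-3/rrf-1) and 91% (rrf-3/ergo-1) of genes changed 4-fold were called, and 100% of those changed 8-fold; 0 unchanged genes were called. For 26-nt reads in IP and input, 55% of 20 genes changed 4-fold and 100% of those changed 8-fold were called, and 0 of 111 unchanged genes. Of 2000 simulated intervals 96.5% held the true ratio, and lists of 30 lowered genes had percentiles of 0. Simulations held counting error alone, not variation between animals.

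Alternatives tried were other denominators (all reads, microRNA reads, 21U-like reads), other lengths (25 to 27 nt, exactly 22 nt), reads with 1 genomic place, distinct sequences, other read minimums (5, 20 and 25), stricter and looser rules of size, other scalings, and the literature list in place of the IP target genes. Chosen after seeing the data were the IP less its adult part, 26-nt reads of any strand or place, a wider position tolerance (-60 to 250 bp), leaving out F55G1.15, list medians with reads of 1 place, single genes per all reads and per microRNA read, and single microRNAs, given as shares of microRNA reads, per non-structural read, and the genes higher in rrf-1 than in both other mutants per read of 4 other denominators.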

Results

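Small RNAs of Caenorhabditis elegans were sequenced in 8 samples around ERGO-1, an Argonaute protein that binds 26-nt small RNAs in oocytes and embryos. The samples came from wild-type gravid adults, wild-type adult RNA after beta elimination, embryos as the input and the product of an ERGO-1 immunoprecipitation (IP), and adults mutant for ergo-1 or for the RNA-dependent RNA polymerase genes rrf-1 and rrf-3. Per the labels, animals were grown at 20 C for 60 to 70 h. The files of the 2 beta-elimination samples were byte copies of each other, so they were counted as 1 library, and each of the 7 groups held 1 library. No group had replicates; the intervals in parentheses are 95% exact intervals that cover counting error only, and no difference was tested against a spread between libraries. Genome-matched depth was 2779953 reads for wild type, 5713014 after beta elimination, 5407871 for input and 4487776 for the IP. It was 3487483 reads for ergo-1, 3709937 for rrf-1 and 3203432 for rrf-3.

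The strain label of the input and IP named the same ergo-1 allele as the adult ergo-1 library. Whether those embryos made ERGO-1 protein was not established here. The IP target genes below are defined by their IP/input ratio alone. The wild-type, beta-eliminated, input and IP libraries were cloned after treatment with tobacco acid pyrophosphatase (TAP). The 3 mutant libraries were cloned after phosphatase and kinase treatment (CIP/PNK), so genotype and cloning method could not be told apart in any comparison of a mutant with wild type. Reads of 26 nt antisense to a named gene, called 26-nt reads here, have the length and strand of 26G-RNAs, and antisense reads of 21 to 23 nt, called 22-nt reads here, those of 22G-RNAs. Their initial nucleotide was not read. Reads of 21 nt from piRNA-rich stretches of chromosome IV, on either strand, are called 21U-like and were not counted as 22-nt reads. Shares are of non-structural reads, that is, all reads outside ribosomal, transfer, small nuclear and small nucleolar RNA, and RPM scaling uses the same reads. Single microRNAs and microRNA families are given as shares of microRNA reads unless said otherwise.

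In wild-type adults, 22-nt reads made up 48.4% of non-structural reads (48.4 to 48.5), microRNA reads 12.404%, 21U-like reads 3.71% and 26-nt reads 0.295% (0.289 to 0.302). Embryo input held 64.3% microRNA reads, 12.3% 21U-like reads, 5.84% 26-nt reads (5.82 to 5.86) and 3.24% 22-nt reads. The ergo-1 library held 27.4% 22-nt reads and 0.0318% 26-nt reads (0.0296 to 0.0341). The rrf-1 library held 24.6% and 0.0634% (0.0605 to 0.0663), and the rrf-3 library 22.8% and 0.0161% (0.0146 to 0.0178).

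**Figure D1:**
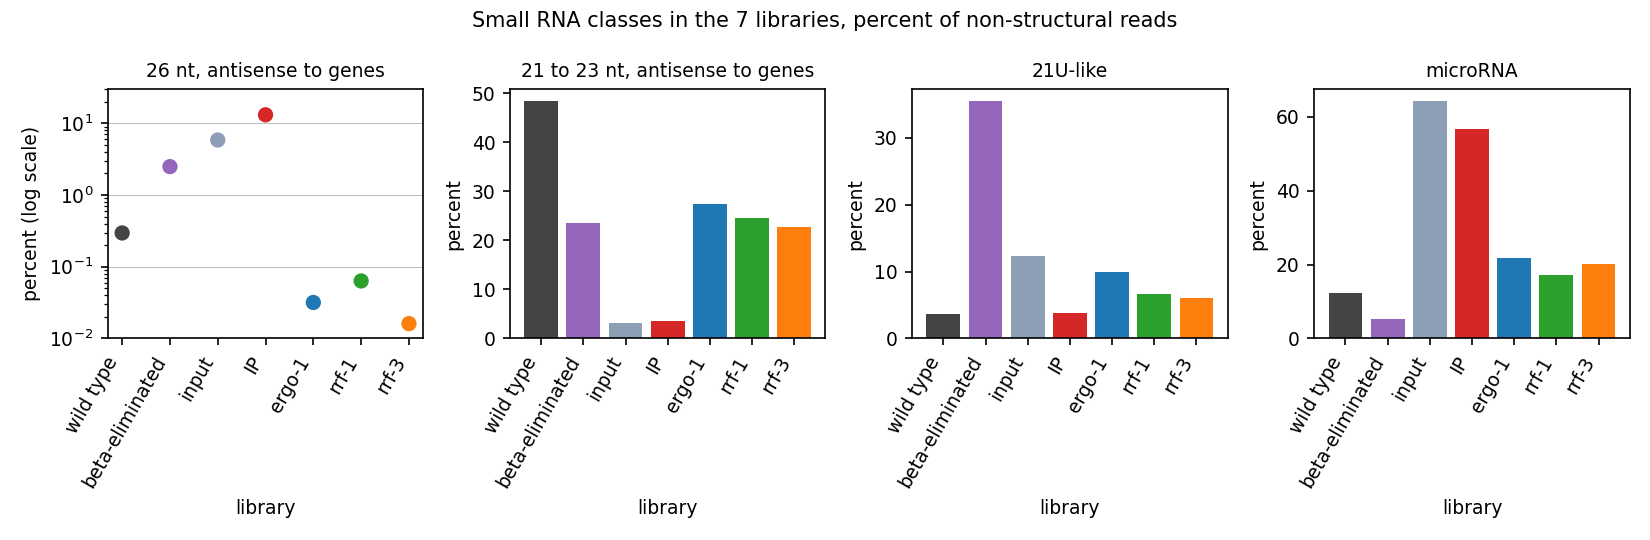
Share of non-structural reads (percent) in each of the 7 libraries for 4 classes of small RNA; the 26-nt panel has a log scale. The share of 26-nt reads was 13.1% in the ERGO-1 IP, 5.84% in input and 0.0161% in the rrf-3 library.

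Beta elimination after periodate oxidation shortens RNAs with an unmodified 3' end, so the comparison with untreated RNA asks which classes are protected. The share of 26-nt reads was 8.41 times that of untreated adults (8.23 to 8.60) and the share of 21U-like reads 9.58 times (9.52 to 9.64). The share of 22-nt reads was 0.487 times (0.486 to 0.488) and that of microRNA reads 0.431 times (0.429 to 0.433). Shares within a library are relative: per 21U-like read, the 26-nt ratio was 0.878, and per microRNA read the 22-nt ratio was 1.13, so these classes changed places around 1 with the denominator.

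Of 135 genes with at least 10 reads of 26 nt in both libraries together, 91 had a ratio wholly above 2 and 1 a ratio wholly below 0.5. The largest by the lower end of the interval were the long intergenic RNA linc-68 at 28.4 (14.3 to 66.2; 467 and 8 reads), F39F10.4 at 18.01 (10.43 to 34.1) and Y37E3.30 at 10.54 (9.57 to 11.64; 9356 and 432 reads). They were followed by linc-11 at 10.49, linc-8 at 10.1, Y57G11C.51 at 11.5, Y37E11B.2 at 10.43, F56D6.17 at 19.6, F52D2.6 at 10.9 and Y105C5A.14 at 10.1. The gene with a lower ratio was Y47H10A.5, with 17 and 31 reads (0.267, 0.139 to 0.498); per microRNA read its interval reached past 1, at 0.619 (0.321 to 1.154).

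For 22-nt reads, scaled to all 22-nt reads, 5474 genes were tested, of which 126 were higher and 15 lower after beta elimination. In the literature list of ERGO-1 target genes, 0 of 28 measured members (here and for the lists below, members with at least 10 reads) passed the rule in either direction; their median log2 ratio was -0.86, below all 10000 random lists of matched level. Whether this list rests in part on these same libraries was not known here, so it is not independent evidence. Among its members with most reads, E01G4.7 had 2962 and 6007 reads (0.493, 0.472 to 0.515) and E01G4.5 2962 and 5717 (0.518, 0.495 to 0.542). Small-RNA pathway genes had a median of -0.62 over 46 members (percentile 0.86) with none past the rule; eri-6, a helicase gene of the ERGO-1 pathway, had a ratio of 1.74 (1.69 to 1.79), sid-1 0.679 and wago-2 0.534. Of 490 pseudogenes measured, 31 were higher and 3 lower, with a median of -0.00, above all random lists, and of 0.45 under median-ratio scaling. Oogenic germline genes (median -0.58, 68 measured), somatic genes (-0.24, 17 measured) and spermatogenesis genes (0.44, 5 measured) had 0 members past the rule; the somatic median was 0.21 under median-ratio scaling, and the spermatogenesis median was -0.60 under RPM scaling. The choice of scaling moved all genes alike in this pair, by -1.04 on the log2 scale under RPM scaling and by 0.45 for median-ratio scaling.

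The comparison of the ERGO-1 IP with its input asks which small RNAs ERGO-1 bound. The 26-nt share was 2.24 times that of input (2.23 to 2.25), at 13.1% against 5.84%, but 1.06 times by distinct sequences and 7.24 times per 21U-like read, and the 21U-like share was 0.310 times (0.308 to 0.312). MicroRNA reads had a ratio of 0.884 (0.882 to 0.885), which turned to 2.85 per 21U-like read, and 22-nt reads of 1.11 (1.10 to 1.12). The IP library also held a part with the 22-nt profile of adults. That part was taken off all classes by a factor fitted on 22-nt reads alone. The 22-nt ratio was then 0.619 (0.614 to 0.624) and the 26-nt ratio 2.39.

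Of 147 genes with at least 10 reads of 26 nt in IP and input together, 56 had a ratio wholly above 2 and are called IP target genes: 28 protein-coding genes, 18 pseudogenes and 10 long intergenic RNAs. None had a ratio wholly below 0.5, and the median ratio of the genes tested was 2.39. The largest ratio was that of F55G1.15, on chromosome IV at file positions 7498080 to 7500927, with 187 IP reads and 6 input reads (38.4, 17.3 to 106.1). Y57G11C.51 followed at 5.78 (5.50 to 6.08; 8756 and 1867 reads), linc-64 at 5.47 (4.48 to 6.73), T05E12.8 at 4.58 (4.42 to 4.74) and F56D6.17 at 4.82 (4.29 to 5.43). The name T05E12.8 is less sure than the others, since it lies in a part of chromosome V where file and annotation positions were not settled. Y37E3.30 had 46775 and 13342 reads (4.32, 4.24 to 4.41), Y51A2A.16 a ratio of 4.55, F52D2.12 of 3.71, F49B2.3 of 4.28 and T16A1.10 of 3.29. F49B2.3 was the exception when only reads with 1 genomic place were counted, at 0.417 (0.00794 to 5.19). That interval also holds 4.28, so such reads did not settle its direction. F55G1.15 differed from the other IP target genes in adults. It had 0 reads of 26 nt in wild type, 1 after beta elimination, 2 in ergo-1, 0 in rrf-1 and 15 in rrf-3, where it was the only IP target gene with a read.

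The IP target genes with most 26-nt reads in the IP were Y37E3.30, linc-8 (28800 reads, ratio 2.77), F39E9.7 (18643, 2.39), T16A1.10 (17387, 3.29), F55C9.5 (16988, 2.41) and F39E9.10 (16760, 2.73), then T05E12.8, Y37E11B.2 (2.26), Y57G11C.51 and C01A2.1 (2.19). More reads came from the pseudogene Y17D7C.3 (63876, ratio 1.75, 1.73 to 1.78) and linc-11 (61219, ratio 1.72, 1.70 to 1.74), which were named after their values were seen and did not pass the rule. Of the 26-nt reads that lay in a single gene, the 10 genes with most reads in each library held 64.1% in the IP and 65.7% in input. Of 28 literature targets measured, 17 were IP target genes and 27 had an interval wholly above 1; F39E9.7 and F55C9.5 passed the rule, while E01G4.7 (1.91, 1.87 to 1.95) and F55C9.3 (2.04, 1.99 to 2.09) did not. Spermatogenesis genes together had 2 reads of 26 nt in each of IP and input.

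**Figure D2:**
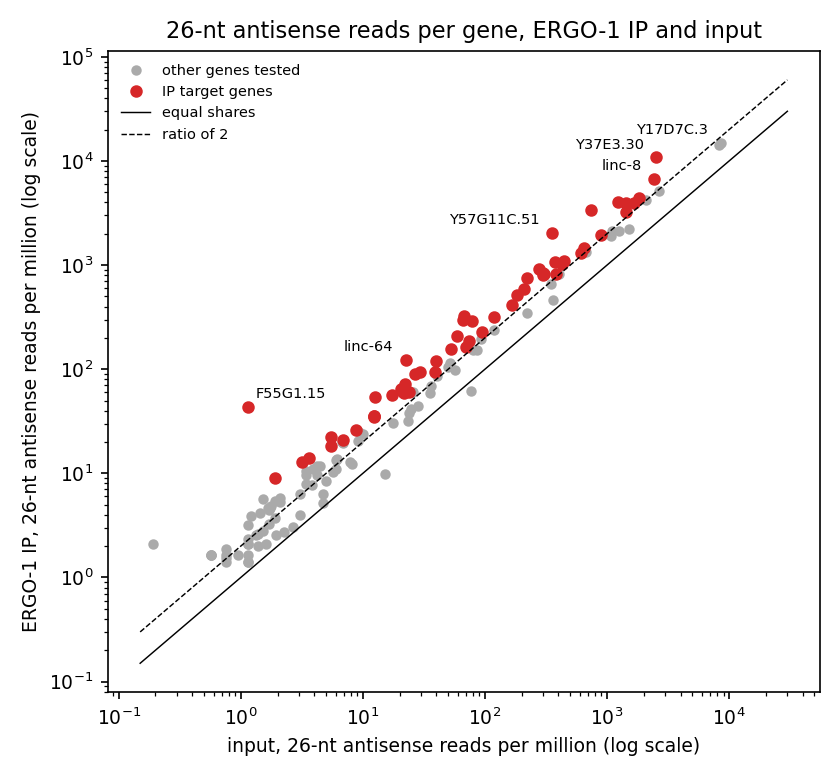
26-nt antisense reads, in RPM (log scales), for each of the 147 genes tested, ERGO-1 IP against input, with a count of 0 drawn at 1 read; red points are the 56 IP target genes. F55G1.15 lies farthest from the line of equal shares, at a ratio of 38.4.

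The 22-nt reads of the same genes went the other way. Scaled to all 22-nt reads, the median log2 IP/input ratio of IP target genes was -0.91 (47 measured, 7 lower and 2 higher by the rule), and that of literature targets -1.06 (26 measured, 4 lower and 1 higher), both below all random lists. With the adult part taken off, pooled 22-nt reads at the IP target genes stood at 0.933 of their input share (0.910 to 0.956), against 0.498 as deposited (0.486 to 0.511); under RPM scaling it was 0.577 (0.563 to 0.592). The fit itself draws what is left after this step towards input. As deposited, scaled to all 22-nt reads, other lists had medians above 0: small-RNA pathway genes 0.52 (40 measured, 1 higher), oogenic genes 0.45 (64 measured, 4 higher), somatic genes 0.27 (5 measured, none past the rule; -0.11 under median-ratio scaling) and pseudogenes 0.15 (230 measured, 3 higher and 5 lower; -0.22 under median-ratio scaling). Set beside random lists of matched level, small-RNA pathway genes had a percentile of 90.3, oogenic genes of 65.7 and somatic genes of 45.3. Their medians lay inside the range of random lists. Pseudogenes had a percentile of 0.625, below the random range of 0.196 to 0.445, so their median was low for their level. The scaling moved this pair by 0.15 on the log2 scale under RPM scaling and by -0.38 for median-ratio scaling.

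As shares of microRNA reads, the mir-35 to mir-41 cluster, abundant in embryos, was 0.779 times as frequent in the IP as in input (0.777 to 0.781), the mir-51 family 1.38 times and the mir-58 family 0.956 times; per non-structural read the ratios were 0.688, 1.22 and 0.845. The let-7 family, which marks late larvae and adults, was 6.99 times as frequent in the IP (6.42 to 7.63), with 3208 and 640 reads. mir-77 had 2220 reads in the IP and 21 in input (148, 96.3 to 238.8), and mir-71 a ratio of 3.04 (130 and 2.68 per non-structural read). Over all genes, among fits of the 22-nt reads of the IP by input plus 1 adult library, 0.463 of input plus 0.107 of the ergo-1 library left the smallest residual, at 188.7, against 200.6 with rrf-3, 212.6 with wild type, 228.9 with the beta-eliminated library and 349.2 with rrf-1. A fit with input, wild type and all 3 mutants left 188.2, with 0.101 of ergo-1, 0.00650 of rrf-1 and 0 of rrf-3 and wild type. The ergo-1 part of the fit by input and ergo-1 came to 8.34% of all IP reads, 47.7% of its 22-nt reads, 16.4% of its 21U-like reads, 2.41% of its microRNA reads and 0.0152% of its 26-nt reads. The factor was fitted on 22-nt reads alone. The shares of all reads and of the other classes assume that they follow it, which was not measured.

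ERGO-1, RRF-3 and RRF-1 were compared through their mutants, all cloned by CIP/PNK, to ask which of them 26-nt RNAs need. At the 56 IP target genes the rrf-1 library held 441 reads of 26 nt, the ergo-1 library 75 and the rrf-3 library 15. The ergo-1 share was 0.203 times that of rrf-1 (0.157 to 0.259) and the rrf-3 share 0.0418 times (0.0232 to 0.0697); rrf-3 stood at 0.206 of ergo-1 (0.110 to 0.362). All 15 rrf-3 reads lay at F55G1.15. Without that gene the rrf-3 library had 0 reads, at least 119.7-fold below the 441 of rrf-1 and at least 23.5-fold below the 73 of ergo-1. At literature targets, rrf-1 had 292 reads, ergo-1 52 (0.212, 0.155 to 0.286) and rrf-3 1 (0.00421, 0.000106 to 0.0236). At spermatogenesis genes, where other Argonautes are known to bind 26-nt RNAs in sperm-producing animals, there were 5, 2 and 0 reads, too few to show a difference at this depth.

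Over all named genes, 26-nt reads stood at 0.501 of rrf-1 in ergo-1 (0.461 to 0.545), at 0.254 in rrf-3 (0.228 to 0.284), and in rrf-3 at 0.507 of ergo-1 (0.448 to 0.573). For 26-nt reads of any strand or place the order was lost, at 1.20 for ergo-1 and 1.10 for rrf-3 against rrf-1. Against the TAP-cloned wild type, the IP target share of 26-nt reads was 0.0256 in ergo-1, 0.126 in rrf-1 and 0.00528 in rrf-3.

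The next comparison asks whether 22-nt reads at ERGO-1 targets depend on the 26-nt pathway. At the IP target genes the ergo-1 share of 22-nt reads was 0.348 times that of rrf-1 (0.330 to 0.366; 1833 and 5655 reads) and the rrf-3 share 0.383 times (0.362 to 0.405; 1631 reads). Y37E3.30 had 18 reads in ergo-1 and 10 in rrf-3 against 704 in rrf-1, which was 36.5-fold (22.9 to 61.9) and 53.03-fold (28.7 to 111.1) lower, and E01G4.5 had 32 and 14 reads against 946. E01G4.7 stood at 0.299 and 0.178 of rrf-1, while C01A2.1 (1.03 and 0.925), CD4.8 (0.466, 0.376 to 0.576, and 0.427, 0.335 to 0.541) and H16D19.4 (0.743 and 0.693) did not pass the rule. rrf-3 and ergo-1 differed little, at 1.10 (1.03 to 1.18), and the side of 1 changed under RPM scaling (0.918) and with the literature list (0.983). Against wild type the shares were 0.0623 in ergo-1, 0.179 in rrf-1 and 0.0687 in rrf-3, values that carry both genotype and cloning method.

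Gene by gene, 24 of 44 IP target genes with at least 10 reads of 22 nt were lower in ergo-1 than in rrf-1 and 0 higher, with a median log2 ratio of -1.89 when counts of 0 were set at 3 reads. In rrf-3, 22 of 44 were lower and 1, F55G1.15, was higher, with a median of -2.02. Of those with at least 50 reads, 13 of 25 were lower and 0 higher in ergo-1, and 11 of 25 lower and 1 higher in rrf-3. Literature targets had 17 of 25 lower in ergo-1 (median -2.14) and 18 of 24 lower in rrf-3 (median -2.96). All 4 medians were below all 10000 random lists. Against the TAP-cloned wild type, 36 of 52 IP target genes were lower in rrf-1 itself, with a median of -2.45. In ergo-1 44 of 52 were lower (median -3.99), and in rrf-3 40 of 52 were lower and 1 higher (median -3.70). A gene that did not pass the rule against rrf-1 can therefore still be lower than in wild type. For rrf-3 against ergo-1, IP target genes had a median of -0.05 (27 measured, 1 higher; 0.04 under median-ratio scaling) and literature targets of -0.46 (15 measured, none past the rule, percentile 0.68). Scaling moved all genes by 0.15 under RPM scaling and -0.10 by median ratio for ergo-1/rrf-1, by -0.11 and 0.02 for rrf-3/rrf-1, and by -0.26 and 0.10 for rrf-3/ergo-1.

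Of the other lists, oogenic germline genes had medians of -0.06 in ergo-1 (0.09 under RPM scaling) and -0.17 in rrf-3 against rrf-1, with 0 of 68 past the rule in each; klp-7, a kinesin gene, stood at 0.797 and 0.892, and the germ granule helicase gene glh-1 at 1.26 and 1.11. Among somatic genes, 2 of 11 were lower in ergo-1 and 3 of 9 in rrf-3: fat-2, a fatty acid desaturase gene of the intestine, was 11.5-fold lower in ergo-1 (6.99 to 20.1) and 12.11-fold lower in rrf-3 (6.93 to 23.1), and egl-21, a neuropeptide-processing enzyme gene, stood at 0.357 (0.253 to 0.497) and 0.235 (0.149 to 0.358). By the same rule fat-2 and egl-21 were also higher in rrf-1 than in the TAP-cloned wild type. There fat-2 had 30.1 reads and egl-21 22, against 209.1 and 147 in rrf-1. The list medians of -0.26 and -0.59 lay inside the range of random lists (percentiles 9.14 and 5.06), and that of ergo-1/rrf-1 was 0.26 with reads of 1 place. Small-RNA pathway genes had medians of 0.11 and 0.03 (46 measured in each; -0.08 under RPM scaling for rrf-3): ergo-1 was higher and rrf-3 lower in its own mutant, parn-1, a poly(A)-specific ribonuclease gene, stood at 2.15 and 2.31, and eri-6 at 1.05 and 1.11. parn-1 passed the rule in rrf-3 alone, and no longer did so per microRNA read (1.83, 1.62 to 2.07). Of the spermatogenesis genes, 4 and 3 were measured and none passed the rule, with spe-41 at 2.26 and 2.13. Pseudogenes had 12 higher and 26 lower of 429 in ergo-1 (median 0.08; -0.02 under median-ratio scaling) and 13 higher and 27 lower of 423 in rrf-3 (median 0.13); Y39E4B.14 stood at 0.986 and 1.10.

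**Figure D3:**
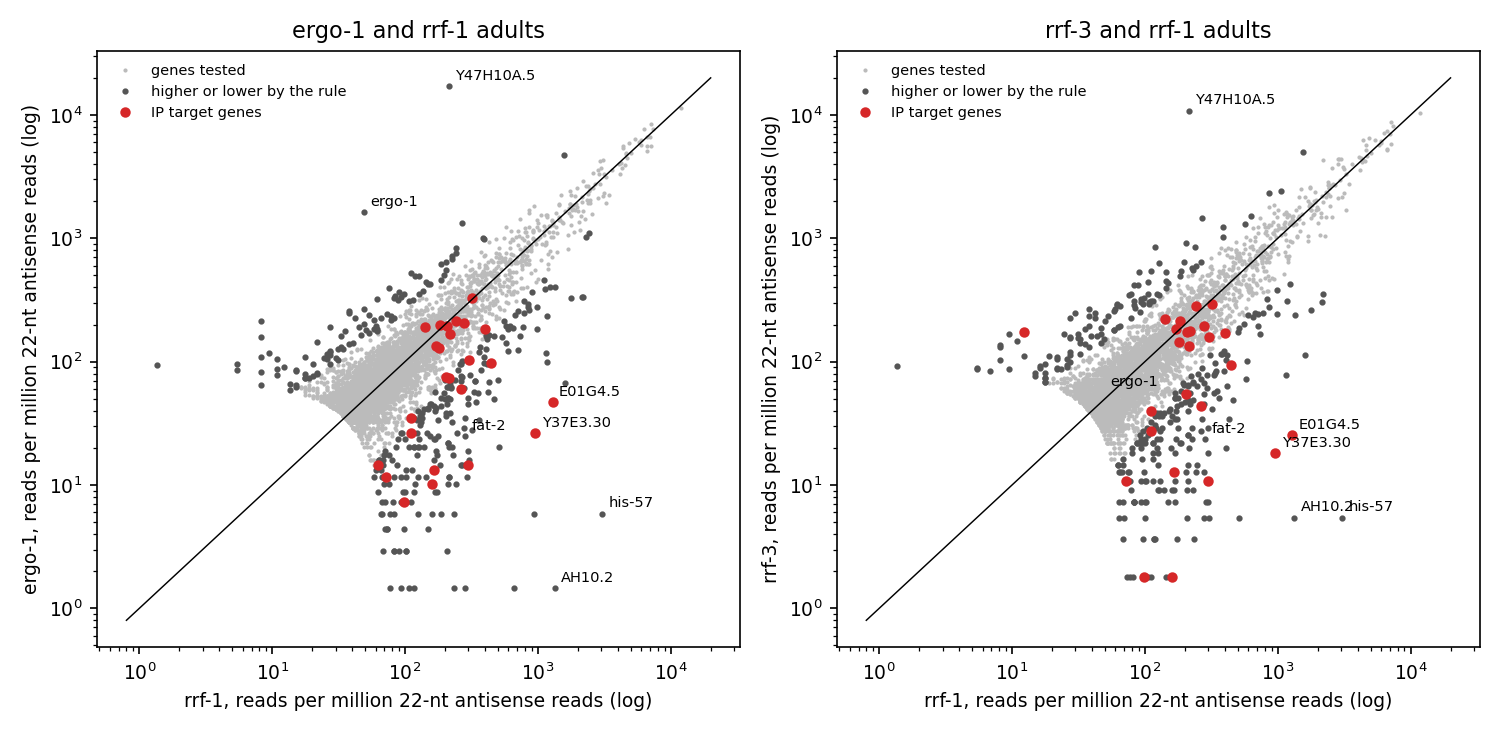
22-nt antisense reads per gene, in RPM of that class (log scales), in ergo-1 (left) and rrf-3 (right) against rrf-1; counts of 0 are drawn at 1 read. Dark points passed the rule of size, and red points are IP target genes, of which Y37E3.30 had 18 and 10 reads against 704 in rrf-1.

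By gene, 22-nt reads differed more between rrf-1 and the others than between ergo-1 and rrf-3. In ergo-1 against rrf-1, 99 of 4466 genes were higher and 225 lower, in rrf-3 against rrf-1 116 of 4097 were higher and 214 lower, and in rrf-3 against ergo-1 11 of 3947 were higher and 7 lower. At an interval beyond 4 or 0.25 the counts were 15 and 97, 21 and 90, and 4 and 1. AH10.2 had 980 reads in rrf-1, 0 in ergo-1 (at least 305-fold lower) and 3 in rrf-3 (0.00406, 0.000837 to 0.0119). The histone gene his-57 had 2247 reads in rrf-1, 4 in ergo-1 and 3 in rrf-3 (0.00177, 0.000365 to 0.00519), but it did not pass the rule when reads shared with other places were left out, at 0.320 (0.0565 to 1.24) in ergo-1. The body-shape gene dpy-1 stood at 0.00521 in ergo-1 (0.000131 to 0.0293) and 0.0193 in rrf-3 (0.00395 to 0.0573), and Y41C4A.8 at 0.00627 (0.000158 to 0.0354) and 0.0155 (0.00187 to 0.0569). Among the lowest in rrf-3 were F52G3.8 (376 and 3 reads; 0.0106, 0.00217 to 0.0312), F55C9.3 (222 and 3; 0.0179, 0.00367 to 0.0531), F55C9.5 (118 and 0, at least 29.6-fold lower) and Y36E3A.2 (106 and 0, at least 26.6-fold lower). Among the lowest in ergo-1 were the serotonin receptor gene ser-4 (0.0141, 0.00169 to 0.0519) and B0454.26 (78 and 0, at least 24.2-fold lower). The TAP-cloned wild type had 2 reads at AH10.2, 8.5 at his-57, 2.1 at dpy-1, 6 at Y41C4A.8, 1.6 at ser-4 and 0 at B0454.26. These genes were higher in rrf-1 than in wild type by the same rule. It had 994.6 at F52G3.8, 2107 at F55C9.3, 1316.4 at F55C9.5 and 955 at Y36E3A.2, which were not.

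Genes with more 22-nt reads in both mutants than in rrf-1 were led by Y47H10A.5, with 11662 reads in ergo-1 and 5991 in rrf-3 against 157 (79.7, 68.1 to 93.8, and 50.7, 43.2 to 59.7). Y102A11A.3 had 64 and 51 reads against 0, at least 22.9-fold and at least 22.6-fold higher. F20D6.10 (26.3 and 16.8), the Notch ligand gene lag-2 (17.4 and 16.3), the spectrin genes sma-1 (13.2 and 16.2) and unc-70 (9.65 and 13.6) and the acid ceramidase gene asah-1 (12.3 and 17.6) followed. F07H5.5 (19.3) and the nuclear migration gene unc-83 (15.5) were among the 10 highest in ergo-1, and F55G1.15 (14.2), F44F1.5 (15.9) and the kinase gene ckk-1 (7.11) among those in rrf-3. The TAP-cloned wild type had 30375.6 reads at Y47H10A.5, 125 at Y102A11A.3, 476 at F20D6.10 and 98.1 at lag-2. It had 158 at sma-1, 103 at unc-70 and 120 at asah-1. By the same rule these 7 genes were lower in rrf-1 than in wild type.

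Between rrf-3 and ergo-1, Y110A2AL.1 had 890 and 4 reads (275.4, 107.2 to 1013) and ZK262.9 334 and 1 (413, 73.7 to 16378); their rrf-1 counts were 683 and 488, so that their reads were near absent in ergo-1 alone. F55G1.15 was higher in rrf-3 (14.9, 7.24 to 35.4), followed by B0261.8 (7.21), ZC204.14 (4.32), ZK262.8, W06A11.4 (3.35), fbxa-216 (3.71), F31E9.6 (3.09) and rnh-1.3 (2.31). The genes lower in rrf-3 were ergo-1 (0.0342, 0.0231 to 0.0488), the cilium gene arl-13 (0.157), lron-4 (0.185), D2096.10 (0.312), F22B7.9 (0.277), Y62F5A.9 (0.335) and F53H4.6 (0.326). fbxa-216, F31E9.6 and rnh-1.3 no longer passed the rule per microRNA read.

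The genes higher in rrf-1 were compared between both other mutants. Among 4041 genes tested in both pairs, 170 were higher in rrf-1 than in ergo-1 and than in rrf-3. Both pairs use the same rrf-1 library, so the lists are not independent. The 170 held 10 IP target genes and 11 literature targets. Of the 170, 149 (87.6%, 81.7 to 92.2) had fewer than 10 reads of 26 nt over the beta-eliminated, input and IP libraries. Among the genes tested, 98.4% (98.0 to 98.8) had that few, and 24 were IP target genes. Against wild type, 83.5% of the 170 were higher in rrf-1 by the same rule, all of them among the 149 with few 26-nt reads. The 170 included AH10.2, the acetylcholine receptor gene acr-17 (194 reads in rrf-1, 9.8 in ergo-1 and 14.7 in rrf-3), the folate transporter gene folt-1 (56, 12 and 7) and the F-box gene fbxa-193 (1570.5, 228.5 and 169), the last 3 named after their values were seen. The 170 lay on all 6 chromosomes, by share of the genes tested from 40 of 833 on chromosome III to 6 of 266 on X. In the other direction, 68 genes were lower in rrf-1 than in both, with lag-2, sma-1 and unc-70 among them. Of these, 57 were also lower in rrf-1 than in wild type by the same rule.

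Shares of microRNA reads also differed between rrf-1 and the others. The mir-51 family was 2.23 times as frequent in ergo-1 as in rrf-1 (2.19 to 2.27) and 2.41 times in rrf-3 (2.36 to 2.45), and lin-4, a regulator of larval timing, 2.93 and 2.68 times. The muscle microRNA mir-1 stood at 0.632 and 0.444, mir-70 at 0.702 and 0.403, mir-79 at 0.480 and 0.453 and the let-7 family at 0.656 and 0.628. The mir-35 to mir-41 cluster stood at 1.14 and 1.27 (1.44 and 1.49 per non-structural read) and the mir-58 family at 1.05 and 0.929 (1.33 and 1.09 per non-structural read). The rrf-3 value of the mir-58 family was the one ratio of this paragraph that changed its side of 1 per non-structural read. Between rrf-3 and ergo-1, mir-73 had a ratio of 2.32 and mir-74 of 2.29.

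Reads along the targeted genes were used to check the labels; the positions of the deletions are not given in the sources used here, so the longest stretch free of reads of either strand and any length was taken in each gene's own mutant. In the ergo-1 library, ergo-1 carried 1123.4 reads of 22 nt, all left of the stretch at file positions 1015346 to 1017356 on chromosome V, and 0 right of it; wild type had 41.2 reads left of it, 18 in it and 19.6 right of it. The share of ergo-1 reads was 33.5-fold that of the rrf-1 library (24.0 to 48.0). The stretch was 1429 nt long for rrf-1, at 7646353 to 7647781 on chromosome I, and 3232 nt for rrf-3, at 8163473 to 8166704 on chromosome II. The other adult libraries were thinned to as many reads of that gene as its own mutant had, 10000 times for each library (chosen after the values were seen). A stretch as long came up in 0 draws for rrf-1 (highest 1012 nt) and 0 for rrf-3 (highest 2245 nt). In input, 15 of 16 ergo-1 reads lay right of the stretch of the ergo-1 mutant, where the mutant had 0, and 0 lay in it, which allows up to 20.6%. The IP had 2 reads in the stretch and 6 right of it. Whether the embryos lacked the deleted part could not be decided from reads in the stretch at this depth. At the IP target genes, 26-nt reads were 2.04% of non-structural reads in input and 0.00300% in the ergo-1 library. These libraries also differ in stage and cloning method, so the values do not settle the genotype of the embryos.

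**Figure D4:**
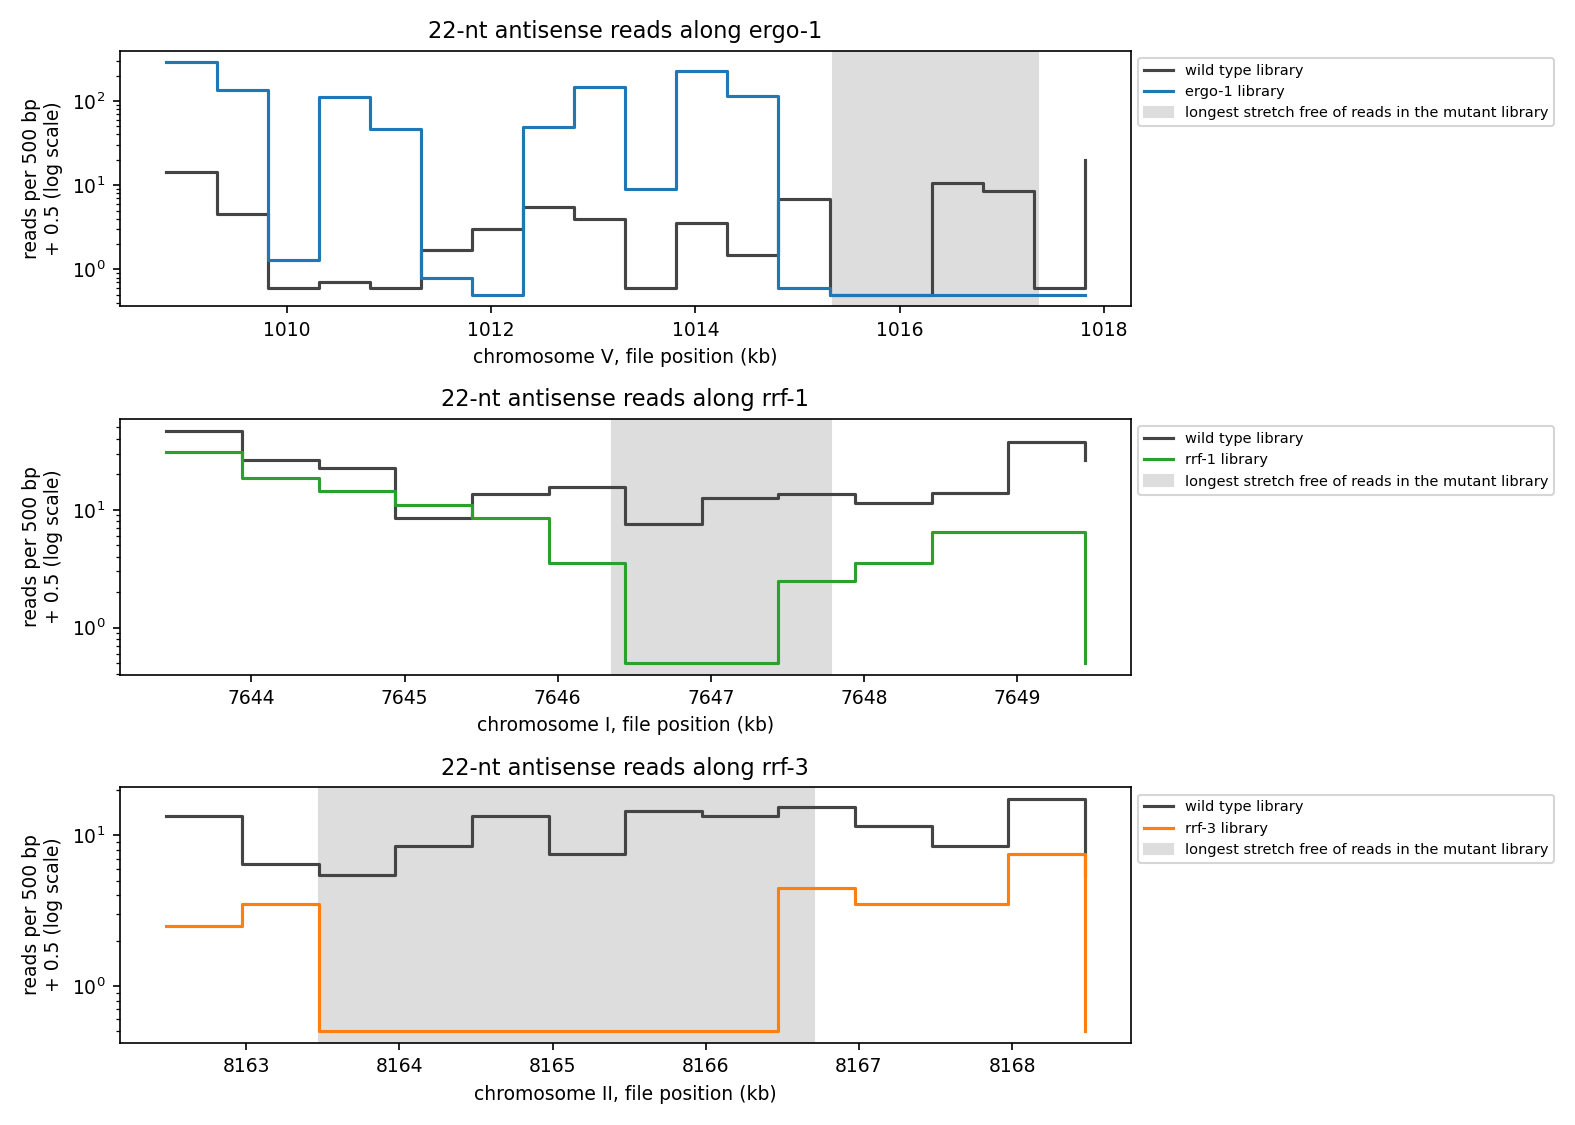
22-nt antisense reads per 500 bp (plus 0.5, log scale) along ergo-1, rrf-1 and rrf-3 by file position, in wild type and in the mutant of that gene; grey marks the longest stretch without a read of either strand and any length in the mutant library. The ergo-1 library had 1123.4 reads left of its stretch and 0 right of it.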

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

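All tests in this part were chosen after the result was seen. Both results below were singled out because they are signals in reads that the comparisons of the report do not use.

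Of 26-nt reads outside named genes, the share in the ERGO-1 IP was 2.11 times that in input (2.097 to 2.118), close to the 2.24 of 26-nt reads antisense to named genes. They were concentrated: 10 windows of 1000 bp held 63.004% of such IP reads. By file position, the window with most was 17073000 to 17073999 on the minus strand of chromosome V, with 42029.5 IP reads and a ratio of 3.33 (3.27 to 3.39), followed by 20379000 to 20379999 on the same strand (38588.5, ratio 1.504) and 2681000 to 2681999 on the plus strand of chromosome II (35716, ratio 3.1002). Chromosome V beyond the limit of naming held 19.2% of these reads, so genes in that part of the annotation were not seen. The window with most reads lies where file and annotation positions were not settled, so whether it lies outside genes is not known. No explanation was tested for this result.

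A set of 1326 abundant 26-nt sequences, with a minimum of 50 reads each, held 880155 reads in the IP and 484591 in input. Of them, 709 were antisense to a named gene. Reads of 18 to 20 nt on the opposite strand, with a 5' end 3 nt inside the 3' end of these sequences, came to 13443 RPM in the IP and 11492 RPM in input. In adults, rrf-1 held 1134 such reads, ergo-1 737 (0.775 of the rrf-1 share, 0.705 to 0.851) and rrf-3 1. At the same positions rrf-1 held 1637 reads of 26 nt, ergo-1 253 and rrf-3 432, of which 422 lay at file positions 2136000 to 2136999 on chromosome II. There were thus 2.91 opposite-strand reads per 26-nt read in ergo-1 (2.52 to 3.37) and 0.693 in rrf-1. The value was 0.130 in wild type, 0.00597 after beta elimination, 0.125 in input, 0.0653 in the IP and 0.00231 in rrf-3. The rrf-1 value was thus itself above that of the TAP-cloned wild type, where genotype and cloning method cannot be told apart.

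Random breakdown of transcripts would spread the reads over the 31 offsets searched, at 3.23% each, but 55.1% of them lay at 1 offset in ergo-1 (52.4 to 57.8). A general loss of short sense reads in the rrf-3 library is argued against by all sense reads of 18 to 20 nt, at 1.13 of rrf-1 (1.12 to 1.14). In ergo-1 all such sense reads stood at 0.814 of rrf-1 (0.805 to 0.822), near the 0.775 of its opposite-strand reads. The rrf-3/rrf-1 ratio of the opposite-strand reads, 0.00108 (2.74e-05 to 0.00605), is the observation itself and so no test of a need for rrf-3 but not for ergo-1. That need cannot be told apart here from strain background, because each genotype is 1 library.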

How the results depend on the processing

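Of 102 alternative values of class, gene-set and target ratios, 94 stayed on the same side of 1, of which 29 lay inside the interval of the value reported. The 65 that moved and the 8 that crossed 1 are given here by setting; where nothing else is said, the cause was not tested. The alternatives named in the methods as chosen after seeing the data are marked by "added".

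Per microRNA read, beta elimination gave 19.5 for 26-nt, 22.2 for 21U-like and 1.13 for 22-nt reads (reversed from 0.487). IP/input gave 2.54, 0.351 and 1.26 for the same classes, and all 26-nt reads 0.395 in ergo-1/rrf-1 and 0.218 in rrf-3/rrf-1. Per 21U-like read, beta elimination gave 0.878 for 26-nt (reversed from 8.41), 0.0508 for 22-nt and 0.0450 for microRNA reads. IP/input gave 7.24, 3.58 and 2.85, the last reversed from 0.884. All 26-nt reads gave 0.333 in ergo-1/rrf-1 and 0.831 in rrf-3/ergo-1, and those of IP target genes 0.135 in ergo-1/rrf-1. A denominator that itself differs between the libraries moves all classes by 1 factor, which is what these values show. With structural reads kept, IP/input gave 2.19 for 26-nt, 1.08 for 22-nt, 0.303 for 21U-like and 0.864 for microRNA reads, and all 26-nt reads 0.448 in ergo-1/rrf-1.

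With reads of 1 place, beta elimination gave 0.473 for 22-nt reads, and IP/input 2.27 for 26-nt and 1.155 for 22-nt reads. All 26-nt reads gave 0.214 in rrf-3/rrf-1 and 0.444 in rrf-3/ergo-1. With 25 to 27 nt, the 26-nt ratio was 5.57 for beta elimination, 0.743 in ergo-1/rrf-1, 0.467 in rrf-3/rrf-1 and 0.629 in rrf-3/ergo-1, and 0.377 for IP target genes in rrf-3/ergo-1. With exactly 22 nt, beta elimination gave 0.469 and IP/input 1.07. With distinct sequences, 26-nt ratios were 1.92 for beta elimination, 1.06 for IP/input, 0.720 in ergo-1/rrf-1 and 0.327 in rrf-3/rrf-1, and for IP target genes 0.320 in ergo-1/rrf-1 and 0.107 in rrf-3/ergo-1. With 26 nt of any strand or place (added), beta elimination gave 8.02, IP/input 2.17 and rrf-3/ergo-1 0.910, while ergo-1/rrf-1 at 1.20 and rrf-3/rrf-1 at 1.10 were reversed. With the adult part taken off the IP (added), 26-nt reads gave 2.39, 21U-like 0.277, microRNA 0.920 and 22-nt 0.619, the last reversed from 1.11. The part removed held 47.7% of the 22-nt reads of the IP. Its factor was fitted on those reads and assumed for the other classes. Without F55G1.15 (added), the 26-nt ratio of IP target genes was 0 in rrf-3/rrf-1 and 0 in rrf-3/ergo-1, since that gene held all 15 rrf-3 reads.

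For 22-nt reads at IP target genes, values are given in the order ergo-1/rrf-1, rrf-3/rrf-1, then ergo-1, rrf-1 and rrf-3 over wild type. Under RPM scaling they were 0.386, 0.355, 0.0353, 0.0913 and 0.0324, with the literature list 0.279, 0.275, 0.0577, 0.207 and 0.0567. With reads of 1 place they were 0.308, 0.335, 0.0513, 0.166 and 0.0557, and without the gene with most reads 0.410, 0.455, 0.0680, 0.166 and 0.0755. For rrf-3/ergo-1, 0.918 under RPM scaling and 0.983 with the literature list were reversed from 1.10.

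With an interval above 1 in place of 2, 117 genes were enriched in the IP rather than 56; other settings gave 45 to 66. With intervals beyond 4 or 0.25, 15 genes were higher and 97 lower in ergo-1/rrf-1, 21 and 90 in rrf-3/rrf-1, and 4 and 1 in rrf-3/ergo-1, as a stricter rule must give fewer.

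For single named genes, 263 of 276 alternative values over 92 genes and comparisons stayed past the rule and 12 did not. The remaining value was that of F49B2.3 in IP/input with reads of 1 place, at 0.417 (0.00794 to 5.19). Its interval spans 1 and holds the 4.28 of all reads, so reads of 1 place did not settle its direction. List medians with reads of 1 place lay inside the bootstrap interval in 31 of 31, although the somatic list turned from -0.26 to 0.26 in ergo-1/rrf-1.

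Depth limited the 26-nt comparisons of mutants: 15 to 441 reads lay at IP target genes, and at most 5 at spermatogenesis genes. No paired analysis was possible because each group is 1 library. Leaving out either beta-elimination sample was not run, since their files were identical.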

Other observations

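All tests in this part were chosen after the result was seen, and the bounds that decide them were set after the values were known.

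mir-8196a, annotated as a microRNA on chromosome X, stood apart from other microRNAs after beta elimination. In wild type 96.8% of its reads were 21 nt long. Its share of non-structural reads after beta elimination was 8.10 times that of untreated RNA (7.69 to 8.53), against a median of 0.395 and a highest value of 3.64 (mir-240/mir-786) for 47 other loci, and 9.58 for 21U-like reads. Its IP/input ratio was 0.399 (0.386 to 0.412), against 0.310 for 21U-like reads; 5 of 56 other loci were lower there, down to 0.222.

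The 22-nt reads of the ERGO-1 IP held a part that input lacked, which came to 47.7% of them. Had that part come from 22-nt reads bound by ERGO-1 at its 26-nt target genes, their share in the IP would be raised. As deposited it was 0.498 of input (0.486 to 0.511). This value speaks only to the source of the part, not to binding as such. Adult-like reads lower the share in any case, since 0.268% of the 22-nt reads of the ergo-1 library lay at these genes. With the adult part taken off, the value was 0.933 (0.910 to 0.956), which the fit draws towards input. Reads of the sequenced ergo-1 library itself mixed into the IP would bring the same fraction of every abundant microRNA, and 6 of 67 loci had fewer reads than that. Against a fitted 0.107 IP reads per ergo-1 read, they ranged from mir-85 at 0.0417 and lin-4 at 0.0490 to mir-48 at 0.0920 and mir-77 at 0.0925. The input part was not taken off, so loci abundant in input could hardly fall below, and the count of 67 says little. The error of the fitted factor was left out. In the IP there were 9.74 reads of ergo-1 per 100 of Y47H10A.5 (7.99 to 11.8), and in input 320 (112 to 1117; 16 and 5 reads). With the fitted input part taken off, the IP had 9.18 (7.49 to 11.2), against 9.63 in the ergo-1 library. The value was 0.260 in wild type, 0.401 after beta elimination, 0.517 in rrf-3 and 22.9 in rrf-1. RNA of ergo-1 mutant adults in the IP sample would give such a value. Both genes were among those fitted, however, so it is no support independent of the fit, and its interval leaves out the error of the fit. A mixture of other adult libraries was not excluded by the 9.18 alone. At which step this part entered was not tested.

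Of the genes with more 22-nt reads in rrf-1 than in ergo-1 and rrf-3, 149 of 170 had few 26-nt reads, AH10.2 and fat-2 among them, but genes with 26-nt reads were more frequent there than among all genes tested (87.6% against 98.4% with few such reads; 10 of 170 against 24 of 4041 were IP target genes). Reads shared between near-identical copies are argued against as the whole cause, since 156 of the 170 genes stayed past the rule with reads of 1 place (his-57 did not). Scaling to all 22-nt reads would need another denominator that differs from it by a large factor. Per non-structural, all, microRNA or 21U-like read, all genes moved by -0.44 to 0.15 on the log2 scale and at least 161 of the 170 stayed past the rule. Only upward moves could take these genes off the list, and the largest was 0.15, so the 4 denominators test scaling little. Against the TAP-cloned wild type, 83.5% of the 170 were higher in rrf-1 by the same rule, all of them among the 149 with few 26-nt reads. The genes with more 26-nt reads did not pass it. The 56 IP target genes together held 0.771% of the 22-nt reads in rrf-1 and 4.30% in wild type. Strain background or culture of the rrf-1 sample cannot be told apart from the loss of rrf-1 here, because each genotype is 1 library.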
